A study of Mus musculus with 4 samples.

How the data were processed

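ChIP-seq was performed on primary salivary gland epithelial progenitor cells of wild-type mice with an antibody to p63 (4A4) or to H3K27ac, and each of these 2 ChIP libraries had its own input library. Per the labels' protocols, immunoprecipitation used a commercial ChIP-seq kit on an automated instrument. Per the submitters' processing notes, the software included Bowtie 1.1.1, a short-read aligner, and MACS2 2.1.0, a peak caller, and the build was mm9; their settings, the peak threshold, and whether duplicates or problem regions were removed are not given in the sources used here. The deposited files are 2 peak lists with 3 columns (chromosome, start, end), with no score, summit, fold enrichment, p-value or strand. Each list is tied to its ChIP library and input by the submitters' labels. Since 1 ChIP library was called against 1 input in each case, no peak could be compared between replicates, and the depth of the libraries is unknown. More depth or a looser threshold lengthens a peak list and widens its peaks, so the numbers of p63 and H3K27ac peaks cannot be compared as amounts of binding.

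The coordinates were checked before use. On chromosome 7, 1072 H3K27ac peaks lie past the last gene of the GRCm38 gene table, so the files were taken as mm9, the build of the submitters' notes. No mm9 genome or annotation was used here, so peaks are given by position, no gene is assigned to a peak, and the planned tests of promoters, of gene lists and of the p63 motif were not run. No peak in either list was repeated and no H3K27ac peaks overlapped each other. The rows of the H3K27ac list are not in genome order: width falls with row number (Spearman rho = -0.44 across peaks), so the list appears ranked, but 85.8% of neighbouring rows are on the same chromosome, where random order would give 5.37%. No ranking value was used here. Starts are printed counted from 1.

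Overlap needed at least 1 shared base. The reference was 100000 circular shifts of all p63 peaks of a chromosome by 1 random offset, within the span from the first to the last peak of either list (2568 Mb in all); this keeps the spacing of the p63 peaks. The span holds stretches where no read can be placed, which lowers the chance level by an amount that was not measured. Two-sided permutation p-values count shifts at least as far from the mean of the shifts as the observed value. Distance classes and width classes used 1000 shifts, alternatives 10000 shifts, and grouping of p63 peaks 1000 random placements. Shares carry Wilson 95% intervals and densities exact Poisson 95% intervals; both cover counting error only. The tests of overlap in both directions, of H3K27ac width and of p63 grouping were fixed before the data were examined. Those of distance and width classes, of coverage at p63 centres, of gaps, of p63 width, of grouped against single sites and of chromosome X were chosen after. Widths were compared by permuting peaks (100000 resamples), with width taken in place of the planned peak score, which the lists do not hold. Coverage at p63 centres was compared with that at the flanks by flipping signs per peak. Peaks are not independent replicates, so each p-value describes placement in these libraries.

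The overlap test was run on simulated data, with p63 peaks placed at random and a known share moved onto H3K27ac peaks. With 30% of 4130 peaks moved, the share recovered over 10 runs averaged 30.0%, with 5% moved it averaged 4.84%, and with none moved 0 of 10 runs reached p under 0.05. The simulated peaks were placed independently and the moved ones centred on H3K27ac peaks, whereas the p63 peaks of the data came in groups. These runs therefore do not give the error rate for grouped peaks. Peaks named in the text were chosen by a rule fixed before the data were examined: with no gene names, the 10 highest-scoring p63 peaks with ties broken by width (with no score, the 10 widest), the 5 widest H3K27ac peaks and the 5 windows of 100 kb with the most p63 peaks. Alternatives covered the definition of overlap, the reference placement, chromosome X, merged H3K27ac peaks, the neighbour distance and, added after the lists were seen, other flanks and domain distances, weighted random placements (5000 per weighting, in 5 random streams) of all p63 peaks and of those within 1 kb of H3K27ac, the widest peaks, the first rows of the H3K27ac list and the removal of 16 p63 peaks in dense windows. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and numba 0.67.0.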

Results

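The transcription factor p63 and acetylated histone H3 were mapped by chromatin immunoprecipitation followed by sequencing (ChIP-seq) in primary epithelial progenitor cells from the salivary gland of adult wild-type mice aged 12 weeks. p63 is a member of the p53 family that marks basal epithelial cells, and it was precipitated with the monoclonal antibody 4A4. H3K27ac, acetylation of a lysine of histone H3, is a mark of active promoters and enhancers. There were 4 libraries in 4 groups of 1: a p63 ChIP, its input, an H3K27ac ChIP and its input. The data are 2 peak lists, each of 1 ChIP set against 1 input, on the mm9 mouse genome. The depth of the libraries is unknown, because the lists hold positions and no read numbers, and there are no replicates. The tests below therefore describe how the peaks of these libraries are placed and do not measure variation between cultures or animals.

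The p63 list held 4130 peaks with a median width of 181 bases (quartiles 145 and 221), the narrowest being 120 and the widest 858 bases. These peaks covered 0.784 Mb, or 0.0305% of the 2568 Mb between the first and last peak of each chromosome. The H3K27ac list held 183757 peaks with a median width of 191 bases (quartiles 155 and 260) that covered 48.0 Mb, or 1.87% of the same span. Of the H3K27ac peaks, 39798 (21.7%) had the smallest width in the list, 150 bases, whereas 3500 (1.90%) were wider than 1000 bases. In the p63 list, 367 peaks (8.89%) had the smallest width. Both lists covered the 19 autosomes and chromosome X.

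The first comparison asked where p63 binding falls relative to active chromatin in the same kind of cell. p63 peaks lay at acetylated chromatin far more often than their number would give by chance. Of the 4130 p63 peaks, 1439 (34.8%, Wilson 95% interval 33.4 to 36.3%) shared at least 1 base with an H3K27ac peak, against 3.34% ± 0.298 (mean and SD of 100000 circular shifts of the p63 peaks within their chromosomes), a 10.4-fold excess (two-sided permutation p = 1e-05, the smallest these shifts can give). A further 471 p63 peaks (11.4%) shared no base with H3K27ac but had an H3K27ac peak within 1 kb on both sides, 13.6 times the 0.838% of shifted peaks. Another 914 (22.1%) had one within 1 kb on 1 side only, 2.14 times the shifted value. In all, 2824 p63 peaks (68.4%, Wilson 95% interval 66.9 to 69.8%) lay within 1 kb of H3K27ac, against 14.5% of shifted peaks. At the other end, 18 p63 peaks (0.436%) were more than 50 kb from any H3K27ac peak, against 8.68% of shifted peaks. The excess held against shifts of at most 1 Mb, which keep p63 peaks in their own neighbourhood and gave 4.96%, a 7.02-fold excess (permutation p = 0.0001, the smallest possible with 10000 shifts). Intervals here cover counting error only, with peaks treated as independent.

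**Figure D1:**
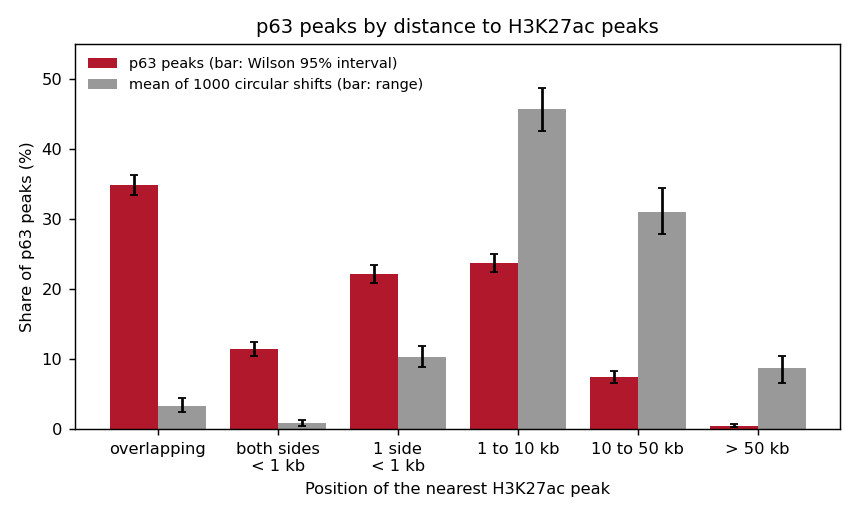
Share of p63 peaks (y axis, %) by the position of the nearest H3K27ac peak (x axis). Red bars are the 4130 p63 peaks with Wilson 95% intervals, and grey bars are the mean and range of 1000 circular shifts. Overlapping peaks made up 34.8% against 3.34% after shifting, and peaks more than 50 kb away 0.436% against 8.68%.

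Seen from the acetylated side, p63 was present at a small part of all H3K27ac peaks and at a larger part of the wide ones. In total 1542 H3K27ac peaks (0.839%, Wilson 95% interval 0.798 to 0.882%) shared at least 1 base with a p63 peak, against 0.0759% after shifting (two-sided permutation p = 1e-05). The share rose with width: it was 0.248% of the 100570 peaks under 200 bases, 1.79% of the 20211 peaks from 300 to under 500 bases, 7.31% of the 3011 peaks from 1000 to under 2000 bases and 15.7% (Wilson 95% interval 12.8 to 19.2%) of the 502 peaks of 2000 bases or more. A wide peak is also hit more often by chance, so each class was set against the shifts: the excess was 4.17-fold under 200 bases, 18.9-fold from 300 to under 500, 28.2-fold from 1000 to under 2000 and 29.9-fold at 2000 or more (permutation p = 0.001 in each of the 6 width classes, the smallest that 1000 shifts can give). H3K27ac peaks with a p63 peak had a median width of 450 bases. The H3K27ac peaks hit by shifted p63 peaks had a median of 215 (95% of shifts between 195 and 245), and those without p63 a median of 190. The difference from the shifted peaks was thus 235 bases. For H3K27ac peaks within 1 kb of p63 it was 94 bases (289 against 195). When H3K27ac peaks within 1000 bases were joined it was 1188 bases (1793 against 605). Width is then the span of the joined peaks with the gaps between them, so this value is not on the scale of the others.

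At finer scale, H3K27ac coverage dipped at the centre of the p63 peaks between higher shoulders on either side. Within 50 bases of the p63 midpoint, 19.2% of positions were covered by H3K27ac peaks, and between 200 and 400 bases away 30.8% were. The difference was -11.6 percentage points (bootstrap 95% interval -12.9 to -10.4; two-sided sign-flip permutation p = 1e-05, the smallest possible). Coverage was lower at the centre than at the flanks for 1633 p63 peaks, higher for 627 and equal for 1870. The flanks span more bases than the centre, so H3K27ac peaks meet them more often by chance. These counts were not set against shifted peaks and are no test of the dip at single sites. Shifted p63 peaks had a flat coverage of 1.97%. Counted per Mb, p63 midpoints were denser in short gaps between neighbouring H3K27ac peaks than inside the peaks that flank these gaps. There were 173 p63 midpoints in gaps under 200 bases, or 91.2 per Mb (Poisson 95% interval 78.2 to 106), and 411 in gaps from 200 to under 500 bases, or 78.4 per Mb. Inside the H3K27ac peaks that flank a gap under 200 bases there were 387, or 32.5 per Mb (interval 29.3 to 35.9), so the gaps held 2.81 times that density (exact 95% interval 2.33 to 3.37). For gaps from 200 to under 500 bases the same ratio was 2.88 (interval 2.48 to 3.36), and for gaps from 500 to under 1000 bases 1.34 (interval 1.09 to 1.66). Inside all H3K27ac peaks, lone ones included, there were 775 midpoints, or 16.1 per Mb, and in gaps from 10000 to under 50000 bases 1.02 per Mb.

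**Figure D2:**
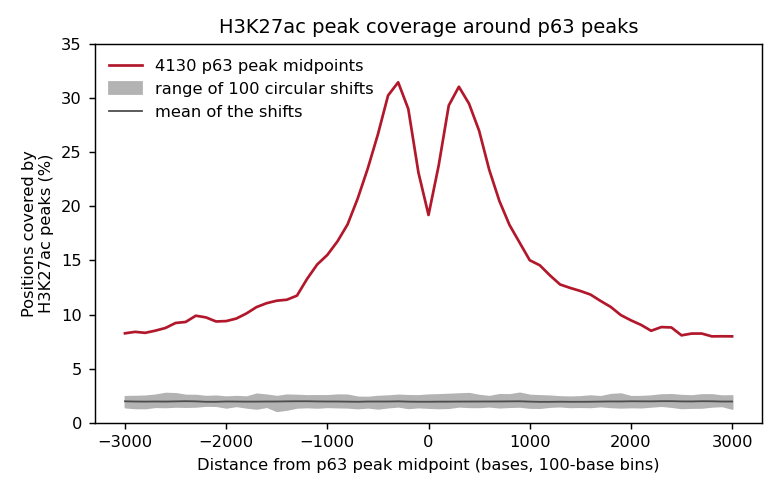
Percentage of positions covered by H3K27ac peaks (y axis) by distance from the p63 peak midpoint in bases (x axis, 100-base bins). The red line is the 4130 p63 peaks, and the grey line and band are the mean and range of 100 circular shifts. Coverage falls to 19.2% at the centre between shoulders that reach 31.5%, while shifted peaks stay near 1.97%.

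Counted another way, largely the same midpoints in short gaps were set against random positions in acetylated domains. These domains were taken as 2 or more H3K27ac peaks at most 1000 bases apart. There were 24666 such domains, with a median span of 1217 bases, and 1466 p63 midpoints fell inside them. Of these midpoints, 834 (56.9%, Wilson 95% interval 54.3 to 59.4%) lay in a gap between H3K27ac peaks. Random positions in the same domains lay in gaps in 36.5% of cases (range of 100000 draws 31.4 to 42.0%; two-sided permutation p = 1e-05). Gaps always lie in the interior of a domain, so these draws cannot tell a preference for gaps from one for the middle. Nor can the densities in gaps given above.

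p63 peaks themselves came in groups. Of the 4130 peaks, 603 (14.6%) had another p63 peak within 10 kb, against 140 expected from uniform random placement on the same chromosomes (range of 1000 placements 89 to 214), a 4.29-fold excess (two-sided permutation p = 0.001, the smallest possible). Placed only at H3K27ac peaks, the same number of sites gave 308 with a neighbour (range 224 to 382), so the excess was then 1.96-fold. Placed at H3K27ac peaks with weights for the width class or the list position that p63 favours, they gave 504 and 507, so the excess was then 1.20-fold and 1.19-fold. These placements put every site at an H3K27ac peak, although 1306 p63 peaks had none within 1 kb. Among the 2824 p63 peaks within 1 kb of H3K27ac, 456 had another of them within 10 kb, against 250 (range 173 to 334) and 251 (range 178 to 321) when as many sites were placed with these weights, a 1.82-fold excess in both cases (two-sided permutation p = 0.0002, the smallest that 5000 placements can give). Grouped sites lay within 1 kb of H3K27ac more often than single ones: the mean share was 85.4% over 279 groups of neighbouring p63 peaks and 65.7% over 3527 single peaks (two-sided permutation p = 1e-05 with groups as units).

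The 5 windows of 100 kb named for their number of p63 peaks differed in acetylation. The window at chromosome 1:195300001-195400000 held 8 p63 peaks and 36 H3K27ac peaks that covered 23005 bases, and 7 of its p63 peaks overlapped H3K27ac. The window at chromosome 2:157200001-157300000 held 6 p63 peaks, of which 4 overlapped its 64 H3K27ac peaks, and the window at chromosome 12:71700001-71800000 held 6 p63 peaks, of which 4 overlapped its 32 H3K27ac peaks. By contrast, the window with the most p63 peaks, chromosome 9:3000001-3100000, held 11 p63 peaks within 35.9 kb and 1 H3K27ac peak of 200 bases. The window at chromosome 2:98500001-98600000 held 5 p63 peaks within 5.08 kb and no H3K27ac peak; it is 1 of 6 windows with 5 p63 peaks and was named as the first of them in genome order. Of the other 5, 4 had p63 peaks that overlapped H3K27ac, and the window at chromosome 2:137200001-137300000 had 15 H3K27ac peaks, with 0 of 5 p63 peaks overlapping them and 3 within 1 kb. None of the 16 p63 peaks of the windows at chromosome 9:3000001-3100000 and chromosome 2:98500001-98600000 lay within 1 kb of H3K27ac. Without them 587 p63 peaks had a neighbour within 10 kb. Whether these windows are regions where reads of repeated sequence pile up, rather than bound sites, was not tested, and the widest p63 peak lies in one of them.

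**Figure D3:**
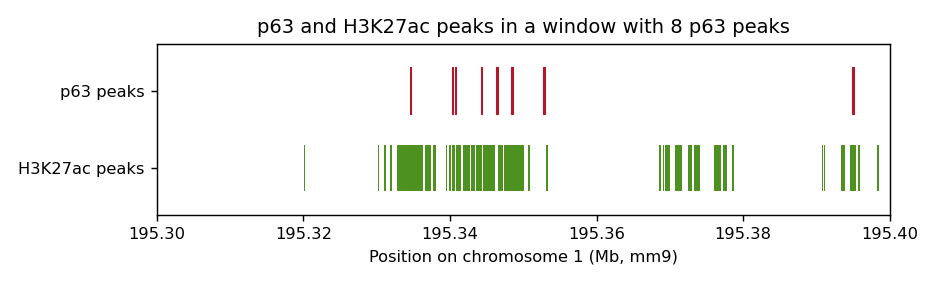
Positions of p63 peaks (upper row, red) and H3K27ac peaks (lower row, green) on chromosome 1 from 195.3 to 195.4 Mb (x axis, mm9). Each block is 1 peak drawn to scale. Of the 8 p63 peaks, 7 overlap 1 or more of the 36 H3K27ac peaks.

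Wider p63 peaks overlapped H3K27ac peaks more often. p63 peaks that overlapped H3K27ac had a median width of 198 bases (quartiles 158 and 239) and the others 173 (quartiles 140 and 210), a difference of 25 bases (two-sided permutation p = 1e-05). Ordered by width, the overlap was 24.9% (Wilson 95% interval 22.3 to 27.6%) for the 1033 narrowest peaks and 50.4% (interval 47.4 to 53.5%) for the 1033 widest, those of 221 to 858 bases. When only the p63 midpoint counted, the difference in width was 8 bases (permutation p = 0.012). A wide peak also meets H3K27ac more often by chance: shifts of the 1032 widest p63 peaks overlapped H3K27ac in 3.92% of cases, against 3.34% for all p63 peaks. Among the 10 widest p63 peaks, 8 overlapped H3K27ac. The peak at chromosome 5:113582047-113582593 (547 bases) lay inside an H3K27ac peak of 1561 bases, and the peak at chromosome 7:26060741-26061263 (523 bases) inside one of 2896 bases. The peak at chromosome 4:117795758-117796264 (507 bases) overlapped an H3K27ac peak of 311 bases at its edge, and the peak at chromosome 17:84298987-84299440 (454 bases) lay inside one of 886 bases. The remaining overlapping peaks also reached past the edge of an H3K27ac peak. They lay at chromosome 4:123265928-123266433, chromosome 12:74396029-74396480, chromosome 2:172459836-172460273 and chromosome 18:65865487-65865924. The peak at chromosome 19:10271298-10271743 (446 bases) missed the nearest H3K27ac peak by 111 bases. The widest p63 peak of the list, chromosome 2:98506629-98507486, lay in the dense window without H3K27ac, 41442 bases from the nearest H3K27ac peak.

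Of the 5 widest H3K27ac peaks, 1 held a p63 peak. The share was 15.7% among the 502 H3K27ac peaks of 2000 bases or more and 0.839% among all H3K27ac peaks. The widest, chromosome 13:31898652-31909700 (11049 bases), had its nearest p63 peak 2306 bases away, at 31912007-31912184. The next ones, at chromosome 11:18912033-18920512 (8480 bases), chromosome 15:74784450-74791872 (7423 bases) and chromosome 4:88582526-88589599 (7074 bases), were 264, 169 and 112 kb from the nearest p63 peak. The peak at chromosome 9:106270322-106277180 (6859 bases) held 1 p63 peak at 106273487-106273737.

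Across chromosomes, the autosomes resembled one another and chromosome X stood apart. The 19 autosomes carried 1.70 ± 0.251 p63 peaks per Mb (SD across autosomes), from 1.34 on chromosome 14 to 2.30 on chromosome 11, and from 62.2 (chromosome 14) to 105 (chromosome 11) H3K27ac peaks per Mb. Chromosome X carried 51 p63 peaks, or 0.316 per Mb, and 30.9 H3K27ac peaks per Mb. Per 100 H3K27ac peaks, X had 1.02 p63 peaks, and the autosomes from 1.99 (chromosome 19) to 2.70 (chromosome 9), so that X stood at 0.448 of the value of all autosomes together. This ratio depended on the peaks counted: it was 0.297 with the 2065 widest p63 peaks and 0.768 with the first 91878 rows of the H3K27ac list, where X came to the level of the lowest autosome (3.47 p63 peaks per 100 H3K27ac peaks in both). Those rows kept 1471 of the 4990 H3K27ac peaks on X, while all 51 p63 peaks on X were still counted. Of the 51 p63 peaks on X, 9 (17.6%, Wilson 95% interval 9.57 to 30.2%) overlapped H3K27ac, against 35.1% on autosomes together, which lies above that interval, and 27.1% on the lowest autosome, chromosome 6, which lies inside it. Within 1 kb of H3K27ac the share was 64.7% on X (33 of 51; interval 51.0 to 76.4%) and 68.4% on autosomes, a difference within the interval.

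**Figure D4:**
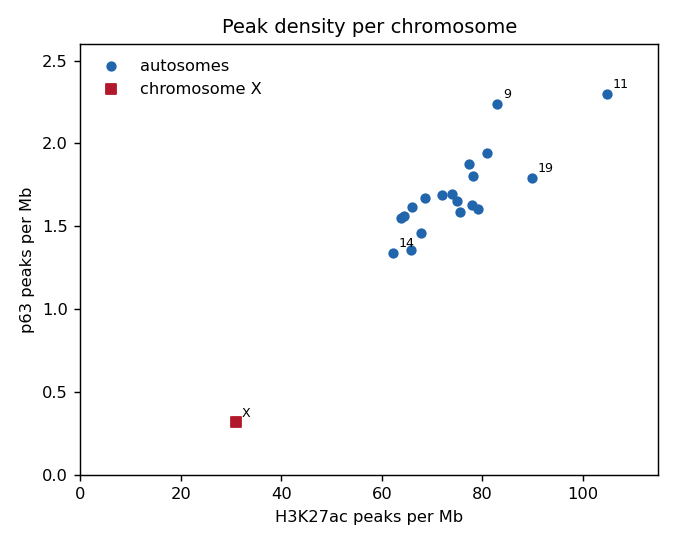
p63 peaks per Mb (y axis) against H3K27ac peaks per Mb (x axis), 1 point per chromosome, with some chromosomes labelled. The 19 autosomes (blue) lie between 1.34 and 2.30 p63 peaks per Mb, and chromosome X (red square) at 0.316 p63 and 30.9 H3K27ac peaks per Mb.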

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

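Every alternative that was run kept the direction and the significance of the overlap of p63 with H3K27ac. Over 12 alternatives the share of p63 peaks ran from 18.8% (p63 midpoint inside an H3K27ac peak) to 68.4% (within 1000 bases) and its excess over chance from 4.71-fold to 15.1-fold. The same held for the difference in H3K27ac width (94 to 1188 bases, 12 alternatives), the share of p63 midpoints in gaps (50.6 to 61.6%, 8), the coverage at p63 centres minus flanks (-20.1 to -7.57 percentage points, 5), the p63 width difference (8 to 26 bases, 6), grouped against single sites (16.0 to 23.4 percentage points, 4) and p63 grouping. The highest H3K27ac width difference, 1188 bases, came from joined peaks, whose width includes the gaps between them. Of 77 alternatives, 74 kept direction and side of the threshold, although sizes moved within these ranges. The excess of p63 grouping, 4.29-fold at first, ran from 1.19-fold with weighted placement of all sites to 8.155-fold for the 1032 widest p63 peaks. Not every alternative could have changed a result. The 16 removed p63 peaks all lacked H3K27ac within 1 kb. Without them the gap share therefore stayed at 56.9% and the overlapping H3K27ac peaks at 1542. Values without a test were held to other limits: peak numbers to 1.5 times (joining took H3K27ac peaks from 183757 to 139150) and the X ratio to the SD between autosomes. Leaving out chromosome X, which took p63 peaks from 4130 to 4079, could not cross the limit for peak numbers. The other 3 concerned the p63 peaks per H3K27ac peak on X over autosomes. This ratio moved from 0.448 to 0.297 (the 2065 widest p63 peaks), 0.551 (the 91878 widest H3K27ac peaks) and 0.768 (the first 91878 rows). The first rows of the H3K27ac list kept 1471 of the 4990 peaks on X, a smaller part than 91878 of 183757 in all. All 51 p63 peaks on X were still counted, so the ratio rose because its denominator shrank more on X. Why H3K27ac peaks on X stand late in the list was not tested. The settings with widest peaks, list rows, weighted placement or 16 p63 peaks removed, those for gaps, centres, p63 width, grouped sites and the X ratio, and those for H3K27ac width other than joined peaks were chosen after seeing the data. The alternatives by peak score, and all those for promoters, gene lists and the motif, were not run. No paired analysis was possible because each group holds 1 library. Depth is unknown, so a p63 site without a called H3K27ac peak is not shown to lack acetylation.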

Other observations

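The tests of random position in domains, of density in gaps, of p63 peaks per H3K27ac peak on X, of the first rows of the list and of weighted placement were chosen only after the result was seen.

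A biologist may want to follow up the p63 sites away from H3K27ac. There were 1306 p63 peaks (31.6%) without an H3K27ac peak within 1 kb, of which 325 (7.87% of all p63 peaks) had none within 10 kb. The 1306 include the 16 p63 peaks of the dense windows on chromosomes 9 and 2. With 1 p63 library and no peak score, false p63 calls among the 1306 cannot be told apart from bound sites. Shifted peaks were farther away more often, with 31.0% at 10 to 50 kb against 7.43% of p63 peaks. Even the narrowest p63 peaks, the 1033 of 120 to 145 bases, lay within 1 kb of H3K27ac in 60.1% of cases, and the widest in 79.8%. With only the midpoint counted, 18.8% of p63 peaks lay inside an H3K27ac peak. The figure for "acetylated p63 sites" therefore moves between 18.8% and 68.4% with the distance allowed.

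Of the 1466 p63 midpoints inside domains of 2 or more H3K27ac peaks, 834 lay in gaps between these peaks. Chance position within a domain was argued against, since this share was 56.9% and the highest of the random draws was 42.0%. A few broad domains did not carry the pattern, since in domains of exactly 2 H3K27ac peaks 56.0% of the 386 midpoints in such domains lay in gaps, above the highest of the draws (45.3%). Every domain begins and ends with an H3K27ac peak, so its gaps are always interior. Uniform draws therefore cannot tell a preference for gaps from a preference for the middle of a domain. Stretches where reads cannot be placed would lower p63 as well as H3K27ac. In gaps under 1000 bases, p63 midpoints were 1.94 times as dense as inside the H3K27ac peaks next to them. The exact 95% interval was 1.75 to 2.16. This ratio pools all such gaps, a p63 peak can be wider than a short gap, and a preference for the middle of a domain would also raise it. It therefore cannot tell whether some gaps hold stretches where reads cannot be placed, which were not mapped here. No biological explanation was tested, and nucleosome positions were not measured.

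Chromosome X held few p63 peaks, and fewer H3K27ac peaks on X did not account for it, with 1.02 p63 peaks per 100 H3K27ac peaks against 1.99 on the lowest autosome. That margin depended on the peaks counted, since with the first 91878 rows of the list X reached the level of the lowest autosome (ratio to all autosomes 0.768). Those rows kept 1471 of the 4990 H3K27ac peaks on X, while all 51 p63 peaks on X were still counted. The rise therefore came from the smaller denominator. Narrower H3K27ac peaks did not account for it either: 50 X peaks had a p63 peak within 1 kb where the autosomal rates of the 6 width classes gave 121, a ratio of 0.412 (Poisson 95% interval 0.306 to 0.543), and rates by 10 stretches of the list gave 0.408. Late place in the list did not account for it at this coarse level. In the first 18376 rows, 5 of 242 X peaks (2.07%, Wilson 95% interval 0.886 to 4.75%) had p63 within 1 kb. On the lowest autosome the share was 6.92%. Neighbouring rows are mostly of the same chromosome, and place within these rows was not matched, so finer differences in place stay open. A single X copy, as in male cells, would lower read coverage in both ChIP libraries and inputs and may push p63 sites under the threshold; it was not tested, because neither the sex of the mice nor the depth was used here, and a true scarcity of p63 sites on X stays open beside it.

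p63 peaks lay close together, with 603 having a neighbour within 10 kb. Placement of all of them at H3K27ac peaks gave 308 (range 224 to 382), which argues against the grouping of H3K27ac peaks, all taken alike, as the whole cause. Weights for the width class or list position that p63 favours gave 504 and 507, and 603 was reached by 1 of 5000 placements under each, but these put every site at an H3K27ac peak. For the 2824 p63 peaks within 1 kb of H3K27ac, the 456 with such a neighbour were 1.82 times the mean of placements with the weights of width classes and lay above the highest placement under both weightings (334 and 321), which argues against favoured width or list position as the whole cause. Other properties of H3K27ac peaks, p63 sites in series and 1 site called as several peaks were not tested and stay open.

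The 16 p63 peaks of the dense windows on chromosomes 9 and 2 were 0 of 16 within 1 kb of H3K27ac, where 68.4% of all p63 peaks were, and they include the widest p63 peak (858 bases). They were singled out after their values were seen, and whether reads of repeated sequence pile up there was not tested.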
